A study of Homo sapiens with 4 samples.

How the data were processed

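Gene expression was measured in MDA-MB-231 cells, an established human triple-negative breast cancer cell line of mesenchymal character. The cells carried either the empty vector pcDNA6/V5-His or the same vector with ZNF217, and were kept as stable transfectants under blasticidin selection (20 µg per ml) in medium holding 10% serum, per the labels' protocols. Each plasmid was represented by the total population of its transfectants, and 2 independent cultures of each population were profiled, per the series' design text. The 4 samples were grouped by the plasmid named in their labels. Total RNA was labelled as biotinylated cRNA and hybridised to Affymetrix Human Genome U133 Plus 2.0 arrays, 1 array per culture, per the labels' protocols.

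The deposited values are linear signal intensities per probe set. Affymetrix Expression Console 1.1 is named in the submitters' processing notes, and the summarisation algorithm is not given in the sources used here. The deposited intensities of every array have the same trimmed mean of 500.1 after 2% of values are left out at each end, so the arrays had been scaled to a common level before deposit. No detection call per probe set was used here. The array medians lay between 67.9 and 73.6, and between 55.3% and 56.5% of probe sets were below an intensity of 100. The number of arrays, 2 per group, limits the precision. Over all probe sets the log2 values of the 2 cultures correlated with Pearson's r of 0.979 (pcDNA6) and 0.978 (ZNF217), and between plasmids r lay between 0.960 and 0.963. These correlations are across probe sets, which are not independent replicates. No pair of arrays held identical values.

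The table held 54675 probe sets. Of these, 62 were control probe sets of the manufacturer, 41091 had exactly 1 gene symbol in the platform annotation, 1801 had several and 11721 had none listed. Entrez identifiers were looked up in a RefSeq gene table of assembly GRCh38.p14, where 41043 of the 41091 were found and 0 symbols needed an update. Probe sets with several symbols or none were left out of the gene tests and are counted in the closing section. Each gene was represented by the probe set with the highest mean log2 value over all 4 arrays, a choice that does not use the groups. This gave 19775 genes, and those at or above the 40th percentile of the mean log2 value, which corresponds to an intensity of 81.4, were tested (11865 genes). Values were taken as log2(intensity + 16). Fold changes on this scale understate the change of dim genes.

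Differences between plasmids were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05 on the adjusted p. The words called, higher and lower refer to this threshold. The fit had 2 residual degrees of freedom and a prior of 7.17. Before the data were examined, 35 gene lists were fixed with 831 entries, of which 760 matched a gene represented on the array by a probe set with 1 symbol. The 32 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera was run again with an estimated correlation, and fry as a further alternative. The estimated correlation rests on 2 residual degrees of freedom, so a list that loses its call there is not thereby shown to be unshifted. Beside each list stands the number of members that pass when p-values are adjusted over the list alone.

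The rule for named genes, also fixed before the data were examined, took ZNF217, the 10 called genes with the largest rise and the 10 with the largest fall whose groups do not overlap, up to 4 called members of each list with the smallest adjusted p (or the member with the smallest p as a value), and ACTB and GAPDH. Members outside this rule are named only to identify small counts, and were chosen after their values were seen. They are TNFAIP2, RUNX2, IL11, PLAAT4, BCL2L1, FOSL1, RSAD2, RRM2, EPCAM, CLDN7, CYP24A1, TAGLN, AXL, CCN1, TGFBR3, HBEGF, LDHA, SLC2A1, SLC2A3, PPP1R15A, DNAJB9, JAG2, HEY1, TP53INP1, PLK3, RREB1, ITGA6, MAGEA6, CYC1 and NDUFA1.

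Background was gauged from the trp control probe sets, which target a bacterial gene that human cells lack. Their 12 values lay between 1.99 and 31.2. Where every array of a group was at or below 31.2, only a lower bound of the fold is given, as the geometric mean of the brighter group over 31.2. For IRX3, LSR, CHRDL1, COX7B2, MMP3, DAPK1, MAGEC1 and ABCC3 only 1 of the 2 arrays of the dimmer group was at or below 31.2, so their differences are imprecise and are not given as bounds. With genes at background in a group held at this bound, the median of the cancer-testis list was -3.29 instead of -3.15, and no other list median changed. Tested genes were also placed in chromosomal order with the RefSeq gene table, only to find which genes neighbour each other, and medians were taken over 464 non-overlapping windows of 25 tested genes. Gene order was shuffled 1000 times to give the limit that the largest window exceeds in 5% of shuffles.

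The test was checked on simulated data with the real means, 11865 genes and 200 changed genes per run over 10 runs. With variances drawn from the fitted prior, 14.2% of genes with a log2 change of 0.5 were called, 65.5% at 1 and 94.2% at 2, and 4.46% of calls were false. With each gene's moderated variance from the fit, 36.1% were called at 0.5, 83.4% at 1 and 98.2% at 2, and 9.15% of calls were false. Over 10 runs of 32 unshifted simulated lists, 2 lists were called, and a list shifted by 0.3 was called in 10 of 10 runs. The simulated genes varied independently, so these runs do not check the list test where members vary together. Each run changed 200 genes, while 3386 were called in the data. The adjustment depends on the share of changed genes, so the shares called in these runs may not hold for the data.

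The alternatives were culture number as a block, each culture left out, quantile normalization, median centring, offsets of 1 and 32, no filter or a 60th percentile filter, the mean of a gene's probe sets, every probe set on its own, eBayes without trend or with a robust prior, a test against a 1.2-fold change, stricter thresholds, and the other list tests. Cyclic loess normalization and removal of the neighbours' median were added after seeing the data. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for reading, array summaries and plots.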

Results

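Gene expression was profiled in MDA-MB-231, a mesenchymal human breast cancer cell line, after stable transfection with a ZNF217 expression plasmid or with the empty vector pcDNA6. ZNF217 is a zinc finger transcription factor whose gene lies in a region that is often amplified in breast cancer. The 2 groups held 2 cultures each, and every culture was measured on its own Affymetrix array. The values are linear signal intensities, and the median over all probe sets was 72.0 and 73.6 in the pcDNA6 cultures and 73.5 and 67.9 in the ZNF217 cultures. RNA quality was similar in all arrays, with a 3′ to 5′ signal ratio between 0.962 and 0.977 for GAPDH and between 1.24 and 1.34 for ACTB. Both cultures of a plasmid came from a single transfected population, so population and plasmid cannot be told apart. The p-values of single genes measure the spread between cultures. Camera's list p-values at the preset correlation compare a list's genes with the other tested genes. They treat genes as nearly independent and do not measure the spread between cultures. With 2 cultures against 2, an exact permutation test cannot give a p below 0.333, and all tests of single genes rest on limma's moderated variances.

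The first question was whether ZNF217 mRNA itself was higher in the cells transfected with its plasmid. It was, by a small margin: the intensity of ZNF217 was 1607 ± 14.0 (SD, n = 2) in the ZNF217 cultures and 1189 ± 37.7 (SD, n = 2) in the pcDNA6 cultures. The log2 difference was 0.43 with a standard error of 0.12 (limma, adjusted p = 0.0297), or 1.35-fold on the scale of intensity + 16. Both ZNF217 cultures (1617 and 1597) lay above both pcDNA6 cultures (1215 and 1162). A single probe set represents the gene, and whether it lies inside the sequence carried by the plasmid is not known, so this value does not check whether the plasmid was transcribed. The 50 tested genes nearest to ZNF217 on its chromosome had a median log2 difference of 0.35, and with this shared shift removed the difference of ZNF217 was 0.082 (adjusted p = 0.694). The call was also lost without pcDNA6 replicate 2 (adjusted p = 0.103), without ZNF217 replicate 1 (adjusted p = 0.105), without ZNF217 replicate 2 (adjusted p = 0.0905) and without the variance trend (adjusted p = 0.0592).

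The second question was which genes differed between the transfectants. The largest differences were losses in the ZNF217 cultures. MMP1, the interstitial collagenase, was among the brightest genes of the pcDNA6 cultures at 24082 ± 687 (SD, n = 2) and was at background in the ZNF217 cultures at 12.3 ± 10.3 (SD, n = 2), which is at least 771-fold lower. CCL2, a chemokine that attracts monocytes, was at least 175-fold lower, and IL13RA2, a decoy receptor of interleukin 13, was at least 160-fold lower. In the other direction RARRES2, which encodes the secreted protein chemerin, rose from background to 843 ± 89.0 (SD, n = 2), at least 26.9-fold. Of the homeobox transcription factors, IRX3 rose by 4.51 on the log2 scale and IRX5 was at least 14.9-fold higher.

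Of 11865 tested genes, 3386 were called (28.5%), 1795 of them higher and 1591 lower in the ZNF217 cultures (limma, adjusted p under 0.05). An unadjusted p under 0.05 was reached by 4745 genes. Called changes under 2-fold numbered 1442 higher and 1143 lower. At least 2-fold changes numbered 353 higher and 448 lower, at least 8-fold changes 10 higher and 66 lower, and at least 32-fold changes 1 higher and 17 lower (0 and 16 with genes at background held at the lower bound of their change, which left the other counts as they were). In all 3386 called genes both ZNF217 cultures lay on the same side of both pcDNA6 cultures, a separation that 65.1% of all tested genes showed and that chance gives in 33.3%. Called genes at background in every culture of a plasmid numbered 26 for ZNF217 and 6 for pcDNA6. The median standard error of a log2 difference was 0.16. Against a fold change of 1.2 limma's treat called 1374 genes, and without the variance trend 2129 were called.

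Among the 10 genes with the largest falls, LINC01088, a long noncoding RNA, was at least 195-fold lower, and BEX5, C5orf46 and the anti-apoptotic BCL2A1 were at least 49.0-fold, 43.3-fold and 43.0-fold lower. CST1, a secreted cystatin, dropped by 6.82 on the log2 scale, from 12436 ± 4694 (SD, n = 2) in the pcDNA6 cultures to 93.5 and 86.4 in the ZNF217 cultures, and COX7B2, a cytochrome c oxidase subunit gene, dropped by 6.74. INHBA, which encodes a subunit of activin A, dropped by 5.52. The adjusted p of the 10 genes lay between 3.58e-08 and 5.33e-06. Among the 10 largest rises, the chloride channel family gene CLIC3 rose by 4.22 and LSR, a component of tricellular junctions, by 3.65, and the organic anion transporter ABCC3 went from 24.2 ± 20.4, near background, to 333 ± 29.3 (SD, n = 2 each). The epidermal gene FLG (filaggrin) was at least 19.8-fold higher, the innate immune sensor NLRP2 at least 12.7-fold, and GPRC5C and FPR1, both G protein-coupled receptors, at least 14.4-fold and 9.88-fold. Their adjusted p lay between 3.40e-06 and 4.76e-04. With an offset of 1 another of the 5 probe sets of ABCC3 was the brightest, and the gene was not called (log2 difference 0.73, adjusted p = 0.182).

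**Figure D1:**
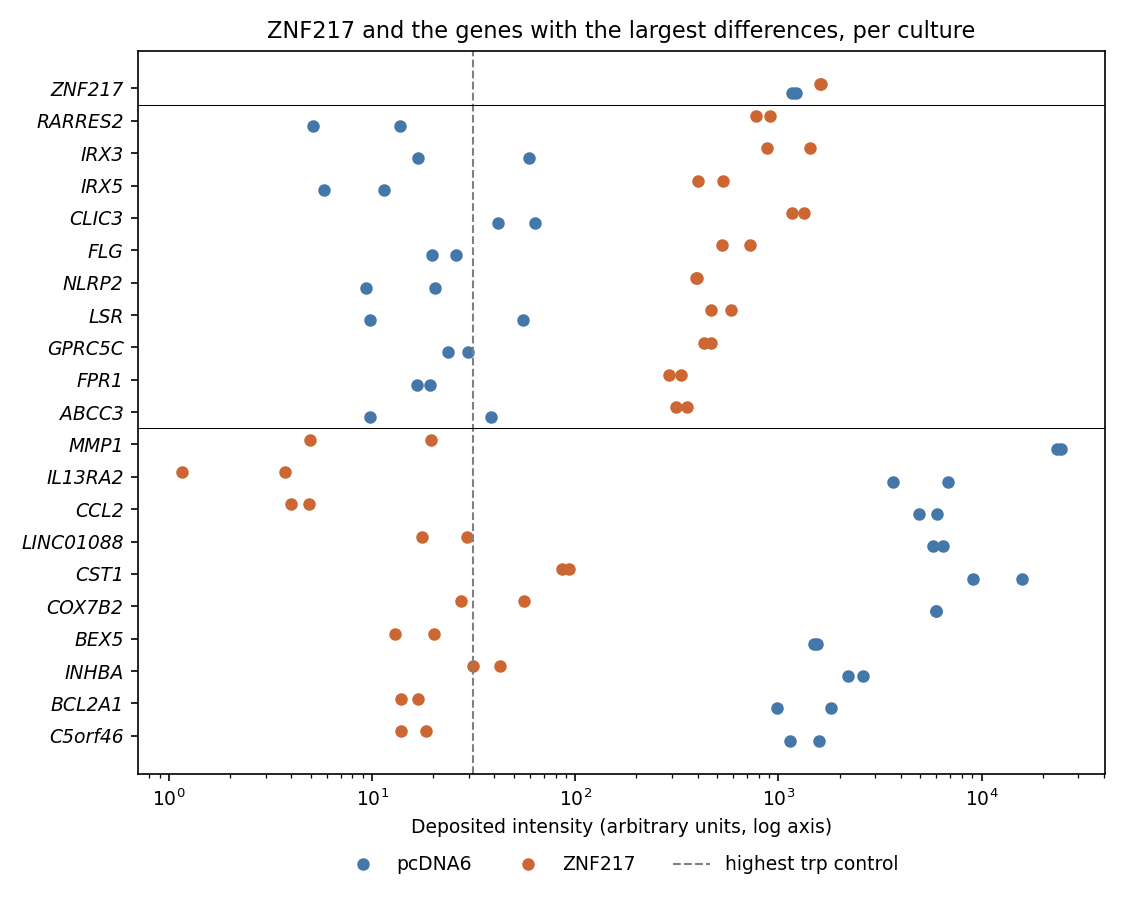
Deposited intensity (log axis, arbitrary units) of ZNF217, the 10 genes with the largest rise and the 10 with the largest fall, 1 point per culture, with the highest trp control value (31.2) as a dashed line. MMP1 lies at 24567 and 23596 in the pcDNA6 cultures and at 19.6 and 4.94 in the ZNF217 cultures, while ZNF217 differs by 1.35-fold.

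Inflammatory genes were mostly lower. Of 23 tested members of the NF-kB and inflammation list, 16 were lower and 1, TNFAIP2, was higher (19 and 1 adjusted over the list alone), with a median log2 difference of -2.12. The median was -1.15 with an offset of 1, -1.13 without a filter and -0.82 with the stricter filter. The cytokine IL1A fell by 5.38, the neutrophil-attracting chemokines CXCL1 and CXCL8 stood at log2 differences of -4.72 and -3.46, and CXCL8 was at 14001 ± 2409 (SD, n = 2) in the pcDNA6 and 1269 ± 314 (SD, n = 2) in the ZNF217 cultures. The list was shifted as a whole (camera adjusted p = 2.22e-12), and its adjusted p was 0.572 with an estimated correlation. Of 14 tested chemokines and their receptors, 9 were lower and 0 higher, and the same counts were found adjusted over the list alone. CXCR4, the receptor of CXCL12, was 31.9-fold lower on the scale of intensity + 16. Other called probe sets of CXCR4 had larger falls on this scale, with log2 differences of -6.88 and -8.49. The chemokine list had a camera adjusted p of 2.6e-07, and 0.538 with an estimated correlation.

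Genes linked to metastasis in sublines of the same cell line were mostly lower. Of 10 tested members of the bone metastasis list, 7 were lower, among them MMP1, the metalloprotease ADAMTS1 (from an intensity of 3214 ± 283 to 84.7 ± 3.81, SD, n = 2 each), CXCR4 and CXCL8, and 2 were higher, RUNX2 and IL11 (7 and 3 adjusted over the list alone). Camera gave an adjusted p of 1.97e-04, and 0.538 with an estimated correlation. Of 15 tested members of the lung metastasis list, 8 were lower, among them MMP1, IL13RA2 and CXCL1, and 2 were higher, PLAAT4 and ID1, an inhibitor of basic helix-loop-helix factors that rose by 2.05. The same counts were found adjusted over the list alone, and the camera adjusted p was 0.00171, or 0.712 with an estimated correlation. The 2 metastasis lists, the inflammation list and the chemokine list share members. Of 5 tested cancer-testis genes, MAGEB2 was lower with a log2 difference of -3.30, MAGEC1 went from 263 ± 52.7 to 23.3 ± 17.9 (SD, n = 2 each), near background, SSX1 and MAGEC2 were at least 20.8-fold and 9.81-fold lower, and MAGEA6 did not pass, also adjusted over the list alone (camera adjusted p = 2.23e-04, and 0.538 with an estimated correlation).

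Genes of antigen presentation were lower on balance. Of 21 tested members 10 were lower and 1, B2M, was higher (10 and 2 adjusted over the list alone). The log2 differences were -2.75 for HLA-DRB1, -2.50 for HLA-DRA, -2.44 for HLA-DPA1 and -1.37 for HLA-DMA. The list's camera adjusted p was 9.92e-05, and 0.684 with an estimated correlation. Most of these genes are neighbours on the chromosome: 14 members lay in stretches whose genes shifted together, and the neighbours of the members had a median difference of -0.40. With the neighbours' shift removed the list's camera adjusted p was 0.0889. The neighbours of a member include other members, so part of the list's own shift was removed as well. This loss therefore does not separate a regional shift from a shift of the list. Of 36 tested interferon response genes 9 were lower and 1, RSAD2, was higher (10 and 1 adjusted over the list alone), with BST2 2.83-fold lower on the scale of intensity + 16 and log2 differences of -1.24 for OAS2, -0.75 for IFITM1 and -0.63 for UBE2L6. For this list camera gave an adjusted p of 0.0339, and 0.744 with an estimated correlation. This call was lost without pcDNA6 replicate 2, where the median difference of the list turned from -0.19 to 0.049 (adjusted p = 0.697), without ZNF217 replicate 1 (adjusted p = 0.280), without the variance trend (0.0649), with the neighbours' median removed (0.0595) and by fry (0.511).

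The lists of apoptosis regulators and of feedback genes of growth factor signalling were shifted downward, though most of their members were not called. Of 23 tested apoptosis regulators 9 were lower and 1, BCL2L1, was higher (10 and 2 adjusted over the list alone). The lower ones included genes of both known functions: the survival gene BCL2A1 and the decoy receptor TNFRSF10D (-1.14), and the death receptor TNFRSF10B (-0.83) and the death-associated kinase DAPK1, which went from 460 ± 33.7 to 30.7 ± 29.2 (SD, n = 2 each), near background. Camera called the list with an adjusted p of 9.58e-04, and 0.538 with an estimated correlation. Of 24 tested genes of the PI3K and MAPK feedback list, 8 were lower and 2 higher (10 and 2 adjusted over the list alone). The immediate early gene EGR1 dropped by 1.67, the MAP kinase phosphatase DUSP6 was 3.02-fold lower on the scale of intensity + 16, and the related DUSP4 dropped by 0.88. The higher ones were the insulin receptor substrate IRS1 (1.14) and FOSL1. The camera adjusted p was 0.00493, and 0.538 with an estimated correlation.

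Cell cycle genes were higher on balance, by small amounts. Of 40 tested members 20 were higher and 1, RRM2, was lower (23 and 1 adjusted over the list alone), with a median log2 difference of 0.38. The mitotic genes NEK2, KIF20A and UBE2C rose by 1.21, 0.87 and 0.81, and the replication licensing gene MCM6 rose by 0.81. As a list they had a camera adjusted p of 2.6e-07, and 0.744 with an estimated correlation. Epithelial genes were also higher on balance, with 7 of 20 tested members higher and 2, EPCAM and CLDN7, lower (8 and 3 adjusted over the list alone). The keratin KRT7 rose from 1375 ± 324 to 7936 ± 793 (SD, n = 2 each), or by 2.53 on the log2 scale, KRT8 and KRT18 rose by 1.17 and 0.70, and the tight junction gene OCLN rose by 1.38. The camera adjusted p of 0.0471 was close to the threshold and was 0.572 with an estimated correlation. It was 0.0724 without ZNF217 replicate 2, 0.103 without a filter, 0.169 with the stricter filter, 0.0505 with the mean of probe sets, 0.0594 without the variance trend and 0.0971 on ranks.

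Of 20 tested cholesterol synthesis genes 7 were higher and 0 lower, and the same counts were found adjusted over the list alone. ACAT2, LSS, MSMO1 and EBP, all enzymes of the pathway, rose by 0.81, 0.75, 0.71 and 0.56. This list had a camera adjusted p of 0.0146, and 0.744 with an estimated correlation, and the call was lost without pcDNA6 replicate 2 (0.0845), without ZNF217 replicate 1 (0.135), with the mean of probe sets (0.0565) and by fry (0.214). Of 17 tested WNT pathway genes 8 were higher and 0 lower, also adjusted over the list alone, among them the ligand WNT7B (1.43) and the receptors ROR1 (1.04), LRP6 (0.96) and FZD7 (0.80). With the mean of its probe sets LRP6 stood at 0.35 and was not called (adjusted p = 0.228). The camera adjusted p was 0.0167, and 0.538 with an estimated correlation. The list of genes near ZNF217 on the long arm of its chromosome includes ZNF217 itself. Of its 10 tested members, 7 were higher, ZNF217 among them, and 1, CYP24A1, was lower (8 and 1 adjusted over the list alone). The transcription factor gene NFATC2 rose by 1.57, the mitotic kinase gene AURKA by 0.74 and the prefoldin gene PFDN4 by 0.37. The camera adjusted p was 0.0167, and 0.684 with an estimated correlation. All 10 members lay in a stretch whose genes were shifted together. With the neighbours' shift removed the list's adjusted p was 0.760, a loss that largely follows from the list being a neighbourhood. It was 0.0562 without a filter and 0.0739 with the mean of probe sets.

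Bright housekeeping genes were slightly higher on the ZNF217 arrays. Of 40 tested ribosomal protein genes 30 were higher and 0 lower (34 and 0 adjusted over the list alone), with a median difference of 0.21, among them RPL27 (0.38), RPL12 (0.34), RPL7 (0.27) and RPS14 (0.27). Of 12 tested reference genes 7 were higher and 0 lower (8 and 0 adjusted over the list alone), among them EEF1A1 (0.27), B2M (0.26), YWHAZ (0.28), GAPDH (0.25, adjusted p = 0.00863) and ACTB (0.20, adjusted p = 0.0171). The camera adjusted p was 4.69e-10 for the ribosomal and 0.00259 for the reference list, and 0.684 and 0.718 with an estimated correlation. The 18 bacterial hybridisation controls, which come from no cell, were also all higher on the ZNF217 arrays, by a median of 0.18, while 17 of 24 probe sets of other bacterial controls, among them all 6 for dap, were lower. After quantile normalization the medians were 0.028 for ribosomal and 0.058 for reference genes, neither list was called, and ACTB and GAPDH were not called. The reference list was also lost with the mean of probe sets (adjusted p = 0.0565) and without the variance trend (0.0643). RPS14 turned to -0.17 with the mean of its probe sets.

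**Figure D2:**
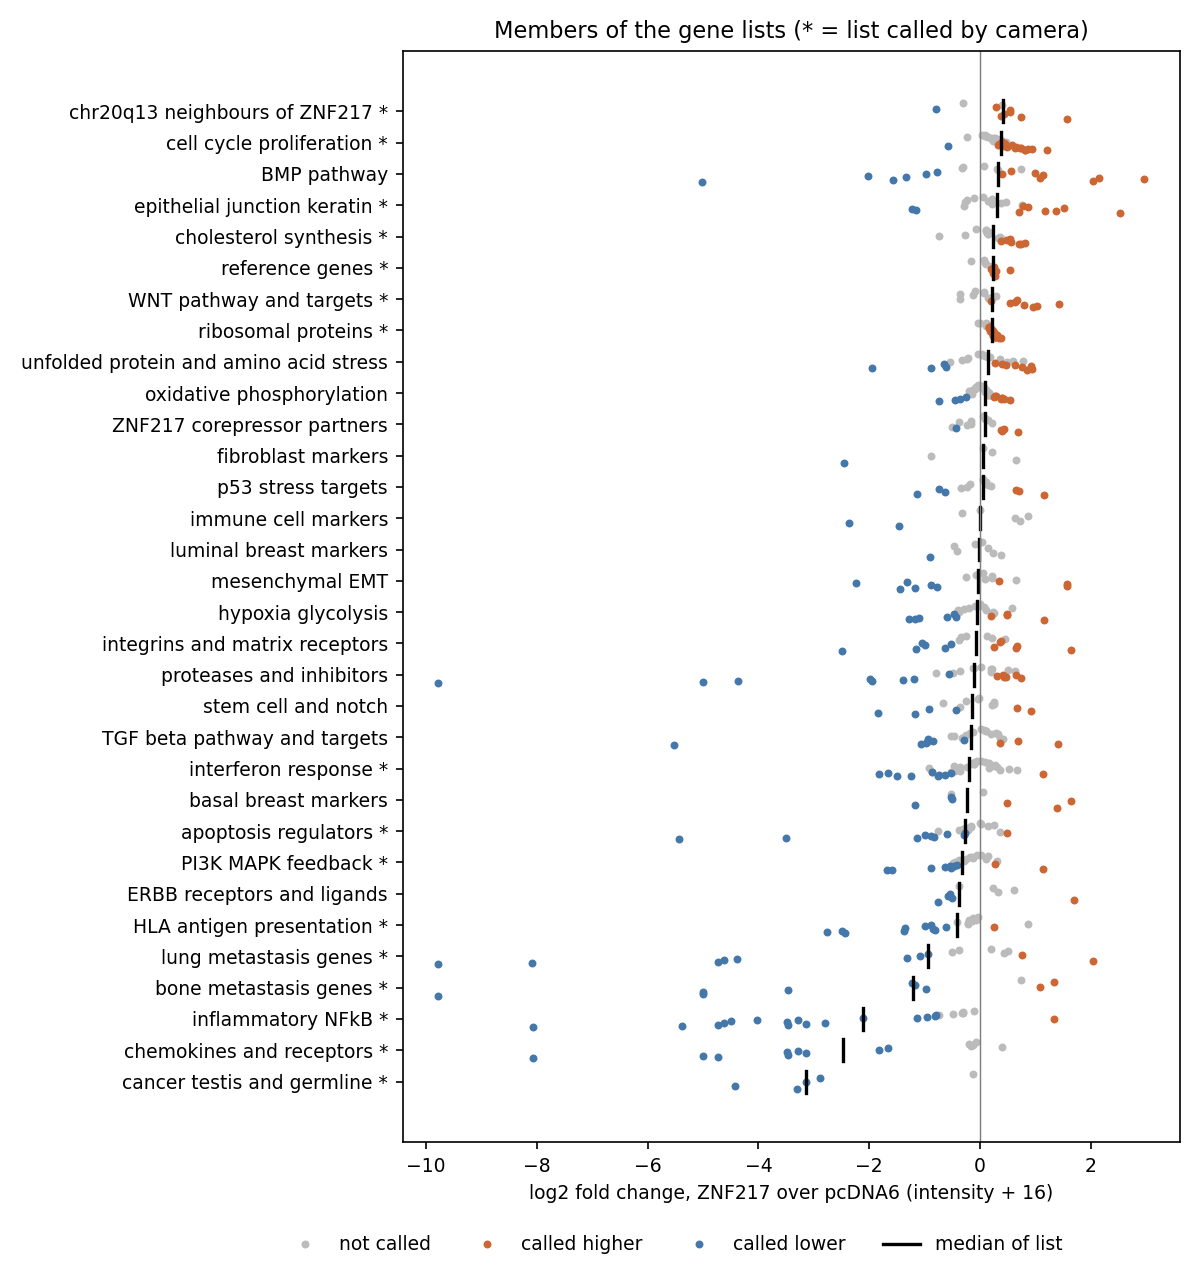
Log2 differences (ZNF217 over pcDNA6, on the scale of intensity + 16) of the tested members of 32 gene lists, 1 point per gene, coloured by call, with the median of each list as a black bar and an asterisk for lists called by camera. Inflammatory genes and chemokines lie far to the left with medians of -2.12 and -2.48 (-1.13 and -0.43 without a filter), while the cell cycle list has a median of 0.38 and the ribosomal list a median of 0.21, which falls to 0.028 after quantile normalization.

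Apart from the luminal markers and the markers of other cell types, the lists that were not called by camera held members called in both directions. Of 17 tested mesenchymal genes 3 were higher (COL5A1, TAGLN and AXL) and 6 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.393, or 0.0421 without pcDNA6 replicate 1). COL5A1, a collagen gene, rose by 1.57, and GNG11, LOX, which crosslinks collagen, and SNAI2, a transcription factor of the mesenchymal state, stood at -1.44, -1.17 and -0.78. Of 26 tested genes of the TGF-beta list 3 were higher (TGFB2, CCN1 and TGFBR3) and 7 lower, also adjusted over the list alone (camera adjusted p = 0.209, or 0.0114 without pcDNA6 replicate 1). The ligand TGFB2 rose by 1.42, and the receptor TGFBR2 and the matricellular gene CCN2 stood at -1.06 and -0.98. Of 20 tested BMP pathway genes 8 were higher and 6 lower (9 and 6 adjusted over the list alone, camera adjusted p = 0.541, or 0.0458 with the stricter filter). The ligand BMP4 rose by 2.97 and its target ID1 by 2.05, and the BMP antagonists CHRDL1 and NOG stood at -5.01 and -1.57. Of 9 tested ERBB receptors and ligands ERBB3 was higher (1.69, or 0.63 and not called with the mean of its probe sets, adjusted p = 0.0988) and ERRFI1 (-0.76), EGFR (-0.51), NRG1 (-0.57) and HBEGF were lower, also adjusted over the list alone (camera adjusted p = 0.489, downward, while the mean was 0.0096 and the median -0.38).

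Of 25 tested proteases and inhibitors 6 were higher and 8 lower (6 and 9 adjusted over the list alone, camera adjusted p = 0.0859). This list passed without pcDNA6 replicate 1 (adjusted p = 2.93e-05), without pcDNA6 replicate 2 (0.0135), without ZNF217 replicate 2 (0.0226), with median centring (0.0280) and with the neighbours' median removed (0.0136). Besides MMP1 and ADAMTS1, the stromelysin MMP3 was lower, from 853 ± 29.1 to 26.4 ± 8.39 (SD, n = 2 each), which is near background, and the metalloprotease inhibitor TIMP3 dropped by 1.95. Of 18 tested integrins and matrix receptors 6 were higher and 6 lower (8 and 8 adjusted over the list alone, camera adjusted p = 0.818), with ITGB4 up by 1.65, ITGA3 up by 0.65, and values of -2.49 for ITGB8 and -1.16 for ITGA2. Of 14 tested stem cell and Notch genes KLF4 (0.93) and JAG2 were higher and ALDH1A3 (-1.84), JAG1 (-1.17), MYC (-0.43) and HEY1 lower (4 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.368). Of 8 tested basal markers S100A2 (1.39), ITGB4 and CAV1 (0.48) were higher and LAMB3 (-1.17), EGFR and ITGA6 lower, also adjusted over the list alone. The basal list's camera adjusted p was 0.923, its mean was 0.11 and its median -0.23. Of 8 tested luminal markers SPDEF alone was called, at -0.91, also adjusted over the list alone (camera adjusted p = 0.818).

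Of 15 tested p53 and stress targets CCNG1 (1.17), MDM2 (0.70) and TP53INP1 were higher and CDKN1A (-1.13), GADD45A (-0.64) and PLK3 lower, also adjusted over the list alone. The camera adjusted p of this list was 0.828, downward, with a mean of -0.0081 and a median of 0.056. Of 15 tested corepressor partners, a list that includes ZNF217 itself, RCOR1 (0.69), CTBP1 (0.40), CTBP2 (0.39) and ZNF217 were higher and RREB1 lower, also adjusted over the list alone (camera adjusted p = 0.704, or 0.0306 by fry). Of 24 tested hypoxia and glycolysis genes ENO2 (1.15), LDHA, SLC2A1 and SLC2A3 were higher and 6 were lower, also adjusted over the list alone, with -1.27 for NDRG1, -1.17 for HK2 and -1.09 for MXI1 (camera adjusted p = 0.469). Of 27 tested unfolded protein and amino acid stress genes 8 were higher, among them DDIT3 (0.94) and the serine synthesis gene PSAT1 (0.85), and PHGDH (-1.95), CHAC1 (-0.89), PPP1R15A and DNAJB9 were lower (11 and 5 adjusted over the list alone, camera adjusted p = 0.358, or 0.00417 by fry). Of 36 tested oxidative phosphorylation genes 8 were higher, among them NDUFB1 (0.54) and ATP5F1B (0.38), and NDUFV2 (-0.74), COX5B (-0.45), CYC1 and NDUFA1 were lower, also adjusted over the list alone (camera adjusted p = 0.343).

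Of 21 tested markers of other cell types 5 were called (23.8%), against 28.5% of all tested genes. Of 7 tested immune cell markers LCP1 (-1.46) and CD14 (-2.37) were lower and 0 higher (2 and 3 adjusted over the list alone), and the camera adjusted p was 0.704, downward, with a median of 0.0038. Of 5 tested fibroblast markers LUM alone was called, at -2.45, also adjusted over the list alone, with a camera adjusted p of 0.653, downward, and a median of 0.057. The endothelial, hepatocyte and melanocyte lists had fewer than 5 tested members and no list test. ROBO4 (-0.97) was the only call among 4 endothelial markers, also adjusted over the list alone. SERPINA1 (-1.51, or -0.96 without pcDNA6 replicate 2) was the only call among 3 hepatocyte markers, of which 3 were lower adjusted over the list alone. Of the melanocyte markers, neither of the 2 tested was called under either adjustment, and MITF stood at 0.11, or -0.10 with the mean of its probe sets.

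Genes that neighbour each other on a chromosome shifted together over long stretches. Of 464 windows of 25 neighbouring tested genes, 25 lay above and 24 below the limit of 0.42 around the median of all genes that the largest window of shuffled gene order exceeds in 5% of shuffles. Between the 2 cultures of either plasmid 0 windows lay outside the limit obtained in the same way. The higher stretches with the largest shifts ran from CEMIP2 to MRPL41 (median log2 difference 0.46 over 350 genes) and from KDM5A to GLIPR1 (0.43 over 375 genes). The lower stretches with the largest shifts ran from DUSP22 to FANCE (-0.43 over 250 genes) and from SH3YL1 to MAP4K4 (-0.41 over 375 genes). ZNF217 lay in a stretch from NCOA6 to UCKL1 with a median of 0.33 over 175 genes. These flanking genes only mark the ends of the stretches and were found after the values were seen. With the median shift of each gene's neighbours removed, 2411 genes were called. The calls of KRT18, KLF4, MDM2, MYC, EGFR, RCOR1, CTBP1, ACAT2, NDUFB1, COX5B and EEF1A1 were then lost, and the differences of GAPDH, RPL12, PFDN4 and ATP5F1B turned below 0. Still called but clearly nearer to 0 were KRT8 (0.66), AURKA (0.40), UBE2C (0.46), LSS (0.45), DDIT3 (0.53), PSAT1 (0.52), HK2 (-0.74), ERRFI1 (-0.38) and NDUFV2 (-0.36). Gene order was taken from assembly GRCh38.p14.

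**Figure D3:**
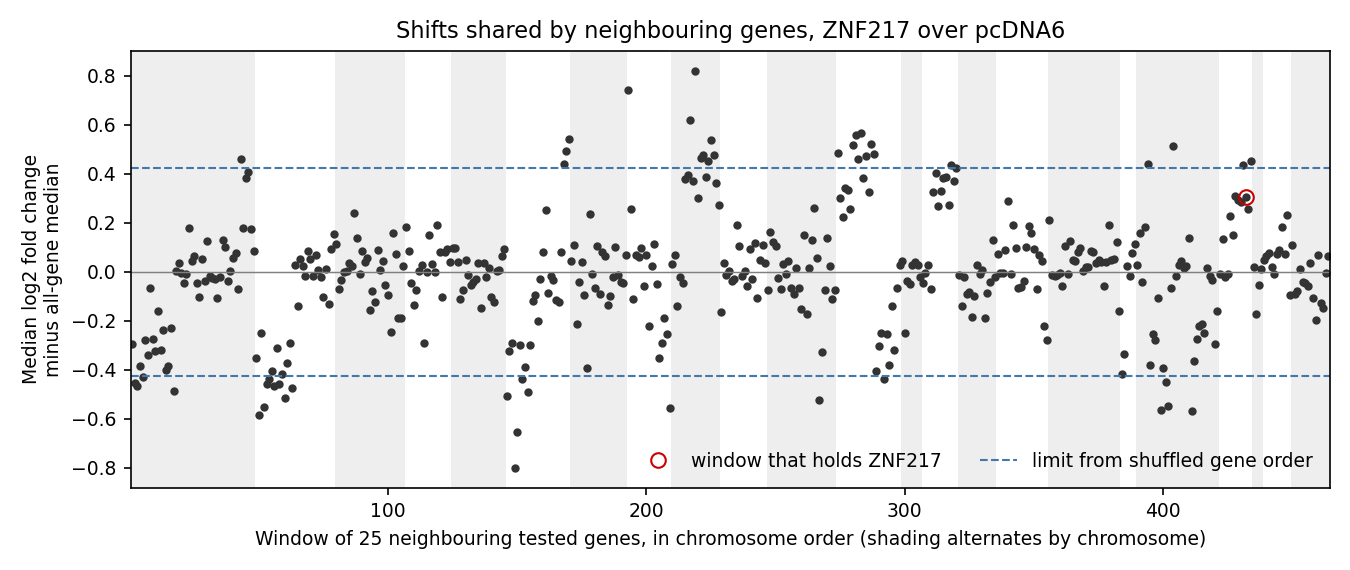
Median log2 difference (ZNF217 over pcDNA6, minus the median of all tested genes) of 464 windows of 25 neighbouring tested genes in chromosome order, with shading that alternates by chromosome and dashed lines at the limit of 0.42 from shuffled gene order. Of the windows, 25 lie above and 24 below the limit, in long stretches of the same sign. The window that holds ZNF217 (red circle) lies among raised neighbours, at 0.31, inside the limit.

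Some calls of single genes depended on the probe sets or the variance model. With the mean of a gene's probe sets the calls of 19 of the 120 called named genes that were tested were lost. Besides ERBB3, LRP6 and RPS14 these were LSS (0.38), HK2 (-0.75), SPDEF (-0.74), SERPINA1 (-0.82), MDM2 (0.40), RCOR1 (0.30), CTBP1 (0.19), CTBP2 (0.38), EBP (0.39), NRG1 (-0.51), PFDN4 (0.13), YWHAZ (0.067), GAPDH (0.18), EEF1A1 (0.19), RPL7 (0.26) and B2M (0.31). Genes called in both ways but clearly nearer to 0 with the mean included LINC01088, GPRC5C, ABCC3 (1.36), IL1A (-3.03), KRT7 (1.33), ALDH1A3 (-0.85), LUM (-1.55), NFATC2 (0.84), OAS2 (-0.80), ROR1 (0.57) and TGFB2 (0.83). Without the variance trend the calls of 20 named genes were lost: ZNF217, ACTB, ATP5F1B, B2M, COX5B, CTBP1, CTBP2, EBP, EEF1A1, EGFR, GAPDH, MYC, NRG1, PFDN4, RPL12, RPL27, RPL7, RPS14, SERPINA1 and YWHAZ.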

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

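The test of ribosomal protein genes after quantile normalization was chosen after the first results had been seen, and the comparison with other bright genes was planned before. The bacterial hybridisation controls, not used in the comparison, differed between the plasmids. All 18 of their probe sets were brighter on the ZNF217 arrays, by a median of 0.18 on the log2 scale (range 0.09 to 0.35). Within these 18 the Spearman correlation of the difference with intensity was 0.10 (p = 0.686). Of 24 probe sets for the other bacterial controls (dap, lys, phe and thr) 17 were lower, among them all 6 for dap (-0.23 to -0.026), whose mean intensities of 211 to 566 overlap the 413 to 796 of the bioB controls. Over all 42 probe sets the correlation was 0.63, and within the 24 it was -0.13. The brighter and the dimmer controls are thus of different kinds, so a trend with intensity and unequal amounts added cannot be separated by them. Among the brightest 10% of tested genes 345 were called higher and 164 lower, and among the next 10% the counts were 230 and 213. An intensity trend left by the deposited scaling is a candidate explanation, and it cannot be told apart from higher ribosomal protein mRNA: the ribosomal median fell from 0.21 to 0.028 after quantile normalization (95% bootstrap interval -0.019 to 0.051) but stayed at 0.12 after cyclic loess, and quantile normalization forces bright ranks to match. Ribosomal genes also lay 0.13 above the 1147 other genes among the brightest 10% (95% bootstrap interval 0.10 to 0.16). This interval includes the planned bound of 0.1. Both bootstrap intervals came from resampling genes as if independent, so they do not measure the spread between cultures.

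Probe sets outside the gene tests also carried differences. Of 13522 probe sets with several gene symbols or with none listed, 3726 passed the filter and 694 of these were called between the plasmids (18.6%), 386 higher and 308 lower (limma, adjusted p under 0.05). These probe sets name no single gene here, and the study's groups have no control for them other than the pcDNA6 cultures.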

How the results depend on the processing

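Cyclic loess normalization and removal of the neighbours' median were chosen after seeing the data, and the other alternatives before. With 2 arrays per group the precision of each gene is limited, and dim genes most, since between 55.3% and 56.5% of probe sets had an intensity below 100 and the trp controls reached 31.2. Of the 3386 calls, 3222 were kept after quantile normalization (17 changed sign), 3060 after median centring and 3207 after cyclic loess (0 changed sign in either). The 3 scalings gave 3297, 3148 and 3341 calls, with between 48.5% and 57.1% of calls higher. Larger changes of the count came from the variance model and the threshold. Without the trend 2129 genes were called, 1054 of them higher, and 2013 of the main calls were kept. With the mean of a gene's probe sets 1105 genes were higher, and 77 main calls had the other sign. Every probe set on its own gave 5219 calls (2726 higher, 2493 lower), where more features were tested. A test against a 1.2-fold change gave 1374 (655 higher, 719 lower), an adjusted p under 0.01 gave 1791 (905 higher, 886 lower) and an added 2-fold limit gave 801 (353 higher, 448 lower). With the neighbours' median removed 1188 genes were higher, 2015 main calls were kept and 138 changed sign. Leaving out 1 culture at a time, where the lone culture is assumed to vary like the other group, gave between 2323 and 3202 calls, with 1146 to 1711 higher (the lowest without ZNF217 replicate 1) and 1177 to 1491 lower.

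The samples share only culture numbers, 2 pairs, and the correlation of the culture deviations between plasmids was 0.13. With the culture number as a replicate block 4118 genes were called and 3383 of the 3386 were kept. The difference of ZNF217 was 0.40 to 0.46 without 1 culture (adjusted p 0.0497 to 0.105), 0.43 without the trend (adjusted p = 0.0592) and 0.082 with the neighbours' median removed (adjusted p = 0.694). It did not pass a test against a 1.2-fold change (adjusted p = 0.395), a threshold of 0.01 or a 2-fold limit. The remaining alternatives gave adjusted p from 0.0157 to 0.0387, and 0.0458 with every probe set on its own and no filter. Camera called 16 lists, and 12 to 17 under the other settings that kept all cultures and the preset correlation. It called 15 on ranks, and fry called 11. Fry gained the unfolded protein and corepressor lists (adjusted p of 0.00417 and 0.0306). It lost the lung metastasis, cell cycle, antigen presentation, ribosomal and reference lists among others (adjusted p of 0.0545, 0.169, 0.102, 0.0588 and 0.101). With an estimated correlation camera called 0 lists, the smallest adjusted p was 0.538 and 1 list had an unadjusted p under 0.05. That estimate rests on 2 residual degrees of freedom, so this setting had little power. Over the called lists the estimated correlations ran from -0.088 (cancer-testis) to 0.77 (cell cycle), against the preset 0.01. They were 0.52 for the inflammation and 0.53 for the ribosomal list. The unadjusted camera p of the cancer-testis list still went from 4.88e-05 to 0.0536. The lost call of that list therefore cannot be put down to correlation between genes. For lists with a high estimate, correlation and low power cannot be told apart.

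The lists whose direction turned were not called in any setting where it did, and the cause was not tested. These were the ERBB list by fry (median -0.38), the p53 list with the neighbours' median removed (0.14) and by fry (0.056), the luminal list without a filter (-0.039) and over the cultures left out (-0.34 to 0.22), and the immune list with the mean of probe sets (0.35). The basal list turned with the replicate block, the stricter filter and ranks (each with a median of -0.23), with quantile normalization (-0.27), without a filter (-0.51), with the mean of probe sets (-0.52) and over the cultures left out (-0.26 to -0.13). The integrin list turned without a filter (0.17), with the stricter filter (0.21), by fry (-0.065) and over the cultures left out (-0.074 to 0.027). Among named genes, the neighbours' median turned ATP5F1B (-0.033), GAPDH (-0.075), PFDN4 (-0.0096) and RPL12 (-0.12), and the mean of probe sets turned MITF (-0.10) and RPS14 (-0.17). No turned gene was called. Of 126 called named genes, ZNF217 included, 19 lost their call with the mean of probe sets (120 tested), 20 without the trend, 16 with the neighbours' median removed and 6 each with quantile normalization and without a filter, and 0 calls were gained. The calls of CTBP1, EBP, NRG1 and UBE2L6 were lost without ZNF217 replicate 1 (adjusted p 0.0516 to 0.0879), those of ACTB, CTBP2, EGFR, GAPDH and YWHAZ without ZNF217 replicate 2 (0.0557 to 0.118), and that of CTBP2 without pcDNA6 replicate 1 (0.0609).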

Other observations

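The tests of normalization, of other differences between the populations and of lost segments for the near-absent genes were chosen after the results were seen, and the remaining tests of this part were planned before. Shifts of neighbouring genes made up 10 stretches of at least 5 consecutive windows with a median beyond 0.2 in the same direction, a definition set after seeing the data. The longest held 15 windows, against 3 in shuffled gene order. Besides the stretches given above, genes from FKBP3 to XRCC3 were higher (median 0.39 over 250 genes), and genes from LINC00115 to CELA3A (-0.35 over 175), SPOCD1 to RNF11 (-0.32 over 150), KRR1 to RNFT2 (-0.30 over 150) and DEDD2 to AKT1S1 (-0.28 over 150) were lower. The stretches held 2400 genes, 20.7% of those in windows, and 33.5% of the calls. Of 1110 calls inside them 94.5% had the direction of their stretch, and 46.3% of the genes inside were called against 23.9% outside.

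Copy number differences between the 2 populations are a candidate explanation of these shifts. In the planned test 49 windows lay outside the limit of shuffled gene order, and 0 windows did so between the 2 cultures of either plasmid, which argues against differences that arose between cultures. For the region around ZNF217, the median of its 50 neighbours was 0.35, and 24 of them were called higher and 2 lower. That median was above the planned upper percentile of random sets of 50 genes (0.15). Such sets hold scattered genes, while neighbouring genes shifted together in many places, so this bound is easily passed by a raised stretch. The window that holds ZNF217 had a median of 0.31 above that of all genes, inside the limit of 0.42. A gain of this region remains a candidate. DNA copy number was not measured here, and a regional change of transcription without a copy number change was not tested. The shift of ZNF217 itself therefore cannot be assigned to the plasmid from these values.

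The genes that were bright in the pcDNA6 cultures and near background in the ZNF217 cultures form another pattern. Array normalization is argued against, because the median log2 difference of the 10 most lowered genes was -6.75 or lower under 3 normalizations (-6.78 as deposited, also with genes at background held at their bound). Their neighbours, up to 25 tested genes on either side, had a median of -0.012 (range -0.24 to 0.13 over the 10 genes). This argues against a loss of broad segments deep enough to bring these genes near background. The lowest of the 10 medians was that of MMP1 (-0.24), and a partial loss of its segment was not excluded. A loss limited to a single gene or a few genes would not move these medians and was not tested. Cultures from another cell line could not be excluded by the genes CDKN2A and CDKN2B, known to be deleted in MDA-MB-231, because a CDKN2A probe set lay at 127 and 24.9 in the ZNF217 cultures and at 85.2 and 76.7 in the pcDNA6 cultures, around the filter intensity of 81.4. Of 6 probe sets of the adjacent gene MTAP, 5 were at 44.1 or lower on every array, and 1 lay at 69.3 and 114 in the pcDNA6 and at 159 and 107 in the ZNF217 cultures, which does not settle it either. Other differences between the 2 selected populations cannot be told apart from an effect of the plasmid for any of the 3386 calls, since each plasmid is represented by a single population, and a response to ZNF217 stays among the open explanations.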
